A study of Homo sapiens with 13 samples.

How the data were processed

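RNA from cells selected with magnetic beads carrying antibodies to CD31, a surface protein of endothelial cells that platelets and many leukocytes also carry, was sequenced from 9 fibrovascular membranes and 4 retinas, per the labels' protocols. The membranes came from vitrectomy surgery for proliferative diabetic retinopathy, and the retinas were non-diabetic and post-mortem. One table holds all 13 samples. Its values are estimated counts of reads per RefSeq transcript, as deposited by the authors, and they were not scaled to library size. Between 81% and 96.5% of genes with a read had a whole-number value in a library (tolerance 0.001). TopHat2 2.0.5, Partek 3, Cufflinks, edgeR and DESeq2 and the genome build hg19 are named in the submitters' processing notes without a role or order. Strand use was not given in the sources used here, so reads of a gene and of an overlapping or antisense gene could not be told apart. Genes with near-identical copies, such as the HLA genes, the haemoglobin genes, HSPA1A and HSPA1B, and pseudogenes such as GSTM2P1 and ARGFXP2, are uncertain because estimated counts split shared reads.

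The table had 52085 transcript entries. In 80 of them a spreadsheet had turned the symbol into a date; 78 were restored through their RefSeq identifiers and 2 were left out. XIST, related X-inactivation genes and Y-linked genes, 122 symbols in all, were removed before any step. Transcripts were summed per symbol and the estimated counts were rounded to whole numbers, which left 22467 symbols with a count. Of these, 92.6% had a model in GENCODE v44 on GRCh37, the same assembly as hg19, from which coordinates were taken (1-based); PECAM1 had none there.

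The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with filterByExpr by group, TMM factors, robust dispersion and robust fitting, and group as the single term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, over 13595 genes tested. CPM are counts scaled to the TMM-adjusted library size. SE is the size of the log2 fold change divided by the square root of the F statistic. It is not a standard error estimated by edgeR. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way and does not compare the list with other genes. Marker scores were the mean log2(CPM + 1) of each cell type list, and the difference of means was tested with an exact two-sided permutation test over all 715 splits of the 13 samples into 9 and 4, adjusted over 16 lists. The test, the 39 lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named RUNX1 and PECAM1; the 8 largest rises and 8 largest falls among called genes with an average log2 CPM of at least 5 and no overlap between the groups; and in each list up to 4 members, the 3 with the smallest p and the most abundant. Some of the genes so named are not reported here. The list of 13 mitochondrially encoded genes could not be tested because those genes had no entry in the table.

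Alternatives were relative log expression, upper-quartile and pan-endothelial scaling factors, DESeq2 1.42.0, limma-voom with quality weights, no low-count filter or an average of at least 10 CPM, an adjusted p under 0.01, a test against a 2-fold change, 1 surrogate variable (sva 3.50.0), the replicate number as a block, each form of retina label alone, retinal genes left out, a pseudocount of 0.25 for the scores, and each library left out in turn. Adjusted p-values that DESeq2 gave as NA stayed NA and were counted neither as calls nor as lost calls. Thinning every library to 140437 reads, leaving out sets of libraries, summed scores and a covariate of reads on olfactory receptor genes were added after seeing the data. Correlations and figures used Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9.

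The main test was tested on simulated data for the membrane and retina comparison, with 200 genes of average log2 CPM of at least 5 changed among 13595 simulated genes, 12840 of which passed the filter. It called 92% of 50 genes changed by -6 on the log2 scale, 60% of 50 changed by -4, 46% of 50 changed by 4 and 94% of 50 changed by 6. Of 12640 unchanged genes 2 were called. The simulated counts were independent between genes, followed a smooth trend of dispersion, and had no outlying library and no background. The 2 calls therefore do not measure the rate of false calls in the real data, where a split other than the real one called 140 genes. Less abundant genes were not among those changed in the simulation.

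Depth ran from 249976 to 9135833 reads in the membranes and from 140437 to 1022155 in the retinas. One read was worth 0.109 CPM in the deepest library and 7.12 CPM in retina 4, before TMM scaling, and the level that a count of 0 allows (3 reads) was 21.4 CPM there. Intervals and such floors cover counting error only, since amplified reads are not independent molecules.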

Results

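Bulk RNA sequencing of CD31-selected cells compared 9 fibrovascular membranes of proliferative diabetic retinopathy, the scar-like vascular tissue that grows from the diabetic retina, with 4 non-diabetic retinas. Membranes 1 to 9 held 5528776, 9135833, 2927133, 2687196, 850070, 2478883, 4497597, 3559689 and 249976 estimated reads. Retinas 1 to 4 held 1022155, 566368, 298712 and 140437. Disease, tissue and surgical or post-mortem origin changed together between the groups and were not separable. The labels do not state that the samples came from separate people, so the p-values measure only the spread between these samples.

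The comparison addressed how gene expression in the selected cells of the membranes differs from that in the selected cells of the retinas. The labels name both as endothelial cells. Collagen and other extracellular matrix genes were higher in the membranes, and genes of rod photoreceptors were lower. POSTN, which encodes the matrix protein periostin, rose from 2.38 ± 3.31 CPM (SD, n = 4) to 333 ± 265 CPM (SD, n = 9). COL1A1, a chain of type I collagen, rose from 27.0 ± 30.0 to 1587 ± 1079 CPM (SD). SAG, the rod arrestin, fell from 401 ± 604 CPM in the retinas to 1.66 ± 4.98 CPM (SD) in the membranes, where 8 of 9 libraries had no read. Its level was 21.3, 19.3, 1288 and 274 CPM in retinas 1 to 4, so the retina mean was carried by retinas 3 and 4.

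By edgeR's quasi-likelihood test 66 genes were higher and 403 lower in the membranes at a Benjamini-Hochberg adjusted p under 0.05, of 13595 tested. At an unadjusted p under 0.05, 1123 were higher and 1533 lower. The spread between libraries was wide, with a biological coefficient of variation of 1.24. In 3.29% of the genes tested the groups did not overlap, against 0.28% by chance. The counts rested on few retina libraries. Without retina 4 they were 20 higher and 145 lower, and with retinas 1 and 2 alone 1 and 7. With retinas 3 and 4 alone they were 17 and 310, and without the 3 libraries under 300000 reads 5 and 9. Of the 403 genes called lower, 1 was still called lower with retinas 1 and 2 alone and 223 with retinas 3 and 4 alone. Without the 3 libraries under 300000 reads, 1 of the 403 was still called lower. Of the 66 called higher, 1, 9 and 5 were still called higher in these settings. Retinas 1 and 2 carried a different form of label from retinas 3 and 4, and the labels do not state whether these were separate collections. With factors from the pan-endothelial list 2.75% of the calls were higher, against 14.1% with TMM factors.

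The largest rises among genes past the threshold without overlap between the groups were in POSTN, OXTR (the oxytocin receptor), LTBP1 (a protein that binds latent TGF-beta), COL1A1, OLFML2B, COL6A2, THY1 (a surface protein of fibroblasts) and COL4A2. By edgeR's quasi-likelihood test the log2 fold change of POSTN was 7.97 (SE 1.44, adjusted p = 0.00234), that of COL1A1 5.98 (SE 1.12, adjusted p = 0.003) and that of COL4A2 5.54 (SE 1.04, adjusted p = 0.003). LTBP1 rose by 6.38, OLFML2B by 5.91, COL6A2 by 5.64 and THY1 by 5.64. OXTR rose by 6.90, with 602 CPM in membrane 5 and between 2.07 and 55.7 CPM in the other membranes. Without membrane 5 the log2 fold change of OXTR was 4.95 and did not pass edgeR's test. The retinas held 2 reads of POSTN, 2 of OXTR and 3 of LTBP1 in all. The ratio of pooled levels was therefore 413 for POSTN (95% interval 114 to 3410, exact binomial), 40.9 for OXTR (11.3 to 338) and 86.1 for LTBP1 (29.5 to 418). POSTN lies on chromosome 13 from 38136720 to 38172981 on the minus strand of GRCh37, COL1A1 on chromosome 17 from 48261462 to 48278993 on the minus strand, and COL4A2 on chromosome 13 from 110958159 to 111165556 on the plus strand.

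Among genes past the threshold with an average log2 CPM of at least 5 and no overlap between the groups, and leaving out LOC, LINC and open reading frame symbols, the largest falls were in SAG, GSTM2P1, IMPG1 (a proteoglycan of the matrix around photoreceptors), ARGFXP2, CADPS (a protein of vesicle release in neurons), PDE6A (a subunit of the rod phosphodiesterase), RBP3 (the retinoid carrier between photoreceptors and pigment epithelium) and MYO5B. Their log2 fold changes were -11.23, -9.36, -9.00, -8.97, -8.76, -8.54, -8.07 and -8.03. ABCA4, a retinoid transporter of photoreceptors, fell by 9.15 with overlap, at 15.0 CPM in membrane 9 and 5.95 CPM in retina 2. For SAG edgeR's adjusted p was 0.000756 (SE 1.67), with 2 reads in all membranes and a ratio of pooled levels of 0.00027 (95% interval 3.27e-05 to 0.000981, exact binomial). MYO5B was at 6095 CPM in retina 4 and between 28.3 and 183 CPM in the other retinas. GSTM2P1, a pseudogene, was at 2795 CPM in retina 4 and at most 71.4 CPM in the others. Without retina 4 the log2 fold changes of MYO5B and GSTM2P1 were -3.54 and -5.16 and did not pass edgeR's test, and that of ARGFXP2 was -5.98 and passed. Without retina 3 that of RBP3 was -5.85 and did not pass. SAG lies on chromosome 2 from 234216462 to 234255701 on the plus strand, and PDE6A on chromosome 5 from 149237516 to 149324356 on the minus strand.

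**Figure D1:**
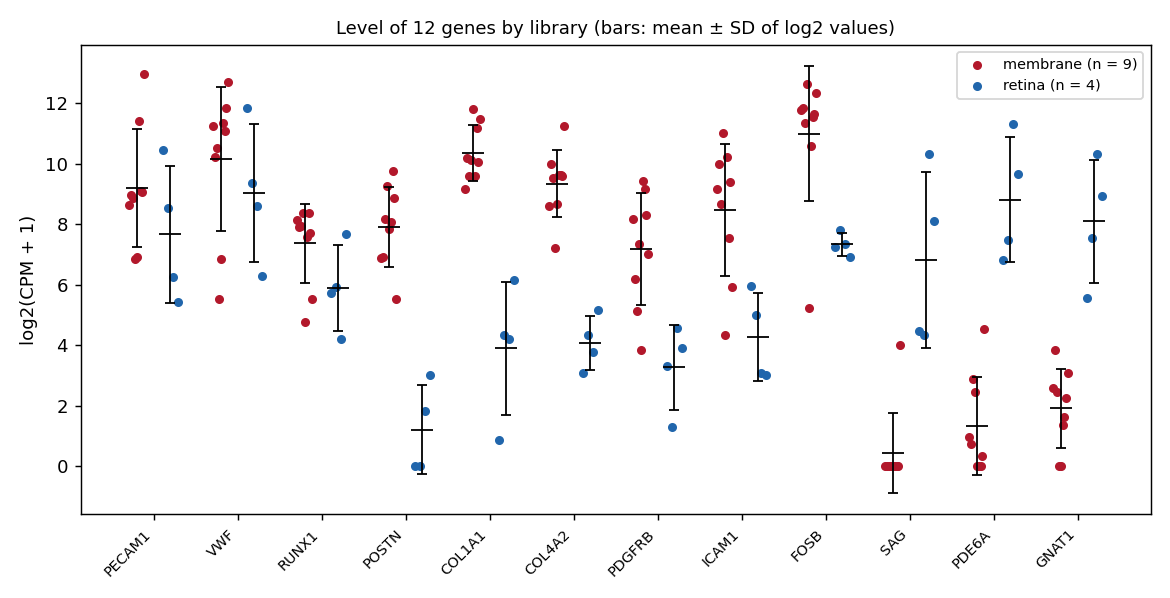
Level of 12 genes as log2(CPM + 1) in each of the 9 membrane libraries and 4 retina libraries; points are libraries and bars are means ± SD of the log2 values. POSTN, COL1A1 and COL4A2 were higher in 9 of 9 membranes than in any retina, while PECAM1, VWF and RUNX1 overlapped between the groups.

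Extracellular matrix genes had the smallest camera p of the 22 gene lists. All 33 measured members of the fixed collagen and matrix list had a positive log2 fold change, with a median of 3.48, and 15 rose over all genes tested and 28 adjusted over the list alone. Type IV collagen of basement membranes was among them, COL4A1 at 1473 ± 1029 CPM (SD, n = 9) against 40.1 ± 30.6 CPM (SD, n = 4). SPARC rose by 2.91 and FN1, fibronectin, by 3.32 on the log2 scale. The list passed camera (adjusted p = 8.73e-22) and remained past the threshold at adjusted p = 0.00701 with an estimated correlation. It also passed fry (adjusted p = 4.12e-06). Its median lay 3.17 above that of all genes with TMM factors and 3.27 above it with relative log expression factors. The fibroblast marker score, given below, also rose, but it is not a separate result, since only 6 of its 13 markers lay outside the matrix list.

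Lists of genes that modify the matrix and of the mesenchymal programme passed camera at the preset correlation and did not pass it with an estimated correlation. Both passed fry (adjusted p = 0.00343 each). In the crosslinking and proteolysis list 1 of 21 members rose over all genes and 5 adjusted over the list alone: TIMP2, an inhibitor of matrix metalloproteinases, by 3.02, a call lost in 22 of 31 alternatives. LOX, which crosslinks collagen, had a log2 fold change of 4.24 without passing (edgeR adjusted p = 0.0755). The list's camera adjusted p was 1.58e-05, and adjusted p = 0.102 with an estimated correlation. In the endothelial to mesenchymal transition list 2 of 15 members rose, the transcription factor SNAI2 by 5.26 and FN1, and 10 adjusted over the list alone. Its camera adjusted p was 3.57e-05, and adjusted p = 0.128 with an estimated correlation. The 5 retina reads of SNAI2 were all in retina 2, and its log2 fold change ran from 4.76 to 10.89 with 1 library left out. ACTA2, smooth muscle actin, was at 401 ± 549 CPM against 33.9 ± 48.5 CPM (SD), edgeR adjusted p = 0.112.

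The TGF-beta, tip cell and Notch lists passed camera at the preset correlation and did not pass it with an estimated correlation. By fry the TGF-beta list passed (adjusted p = 0.0242), and the tip cell and Notch lists did not (adjusted p = 0.0579 each). SKIL, a repressor of SMAD signalling, rose by 3.20 and TGFBI, a matrix protein induced by TGF-beta, by 4.37, which were 2 of the 23 members (3 adjusted over the list alone). SKIL and TGFBI each lost the call in 21 of 31 alternatives, with the direction kept in all. The TGF-beta and BMP list had a camera adjusted p of 0.000262, and adjusted p = 0.262 with an estimated correlation. Of 21 tip cell genes 5 rose (8 adjusted over the list alone), of which 4, SPARC, COL4A1, COL4A2 and NID2, also stood in the matrix list. The other was PLAUR, the urokinase receptor, named after its value was seen. This list had a camera adjusted p of 0.000624, and adjusted p = 0.407 with an estimated correlation. Of 15 Notch genes NOTCH3, a receptor of mural cells, rose by 4.36 (1 adjusted over the list alone; camera adjusted p = 0.00804, and adjusted p = 0.407 with an estimated correlation). None of the 19 VEGF and angiopoietin genes was called by edgeR, in either direction (1 higher and 0 lower at an unadjusted p under 0.05; 0 by DESeq2 and 1, lower, by limma-voom), and the list did not pass camera (adjusted p = 0.154), though it did in 3 of 24 alternatives.

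Inflammatory and immediate-early lists, with 3 called members each, passed camera at the preset correlation and did not pass it with an estimated correlation. Neither passed fry (adjusted p = 0.1535 and 0.0579). ICAM1, an adhesion receptor for leukocytes, rose by 4.62, the chemokine gene CXCL2 by 5.97 and the cytokine gene IL1B by 6.03, which were 3 of the 24 inflammation and adhesion genes (7 adjusted over the list alone). Membranes 5, 7 and 9 had the lowest macrophage scores of the membranes (1.43, 3.20 and 3.28) and the lowest levels of these genes: ICAM1 19.2, 185 and 59.8 CPM, CXCL2 2.95, 54.9 and 22.4, and IL1B 11.8, 605 and 112. In membrane 4 IL1B was at 24860 CPM. The list's camera adjusted p was 0.000166, and adjusted p = 0.449 with an estimated correlation. The immediate-early genes FOSB, NR4A2 and IER3 rose by 4.30, 4.40 and 3.47, which were 3 of the 23 (15 adjusted over the list alone). IER3 lost the call in 20 of 31 alternatives. In membrane 5 FOSB was at 36.9 CPM and NR4A2 at 14.8 CPM, below every retina. That list had a camera adjusted p of 7.15e-06, and adjusted p = 0.424 with an estimated correlation.

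Heat shock, interferon, oxidative phosphorylation and ribosomal lists passed camera at the preset correlation and did not pass it with an estimated correlation. None passed fry (adjusted p = 0.0579, 0.2453, 0.0634 and 0.1597). Heat shock genes had a median of 1.41, interferon-stimulated genes 1.00, nuclear genes of oxidative phosphorylation 0.99 and ribosomal protein genes 0.94, against 0.31 for all genes, and edgeR called 0 of their 15, 23, 22 and 43 members. Their camera adjusted p-values were 0.012, 0.0141, 0.0287 and 0.00935, and adjusted p = 0.472, 0.606, 0.449 and 0.641 with an estimated correlation. Adjusted over the list alone, 0 were called in each. At an unadjusted p under 0.05, 2, 2, 0 and 6 were higher and 0 lower. DESeq2 called 0, 0, 0 and 1 higher and limma-voom 3, 0, 0 and 1. The median of all genes was -0.18 with relative log expression factors, 0.12 with upper-quartile factors and 1.24 with pan-endothelial factors. The ribosomal list lay 0.63 above all genes with TMM factors and -0.76 from them with pan-endothelial factors.

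Genes of phototransduction and the retinoid cycle fell. Of 10 measured members 6 were lower over all genes and 7 adjusted over the list alone, with a list median of -4.59. LRAT, which esterifies retinol in the pigment epithelium, had a log2 fold change of -7.55, with 1439 CPM in retina 4 and none in retina 3, and of -3.77, which did not pass edgeR's test, without retina 4. The list passed camera (adjusted p = 9.89e-07) and had adjusted p = 0.013 with an estimated correlation. It also passed fry (adjusted p = 8.71e-05).

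The lists for RUNX factors, the blood-retina barrier, Norrin and Wnt signalling, antigen presentation, complement and coagulation, hypoxia, glycolysis and the cell cycle did not pass camera, with adjusted p-values of 0.664, 0.596, 0.596, 0.0549, 0.119, 0.996, 0.79 and 0.977. In 9 of 24 alternatives the antigen presentation list passed, in 5 of 24 the complement and coagulation list and in 2 of 24 the glycolysis list. Within them RUNX1T1, a transcriptional corepressor, fell by 3.55, F8, coagulation factor VIII, fell by 3.70, and ENO2, the neuronal enolase, fell by 4.77. The log2 fold change of F8 was 0.13 with pan-endothelial factors and ran from -4.78 to -2.15 with 1 library left out. Retina 1 held 860 CPM of F8, and the other retinas between 35.1 and 161 CPM. The glycolysis list had a median of 0.58 and a mean of -0.14.

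**Figure D2:**
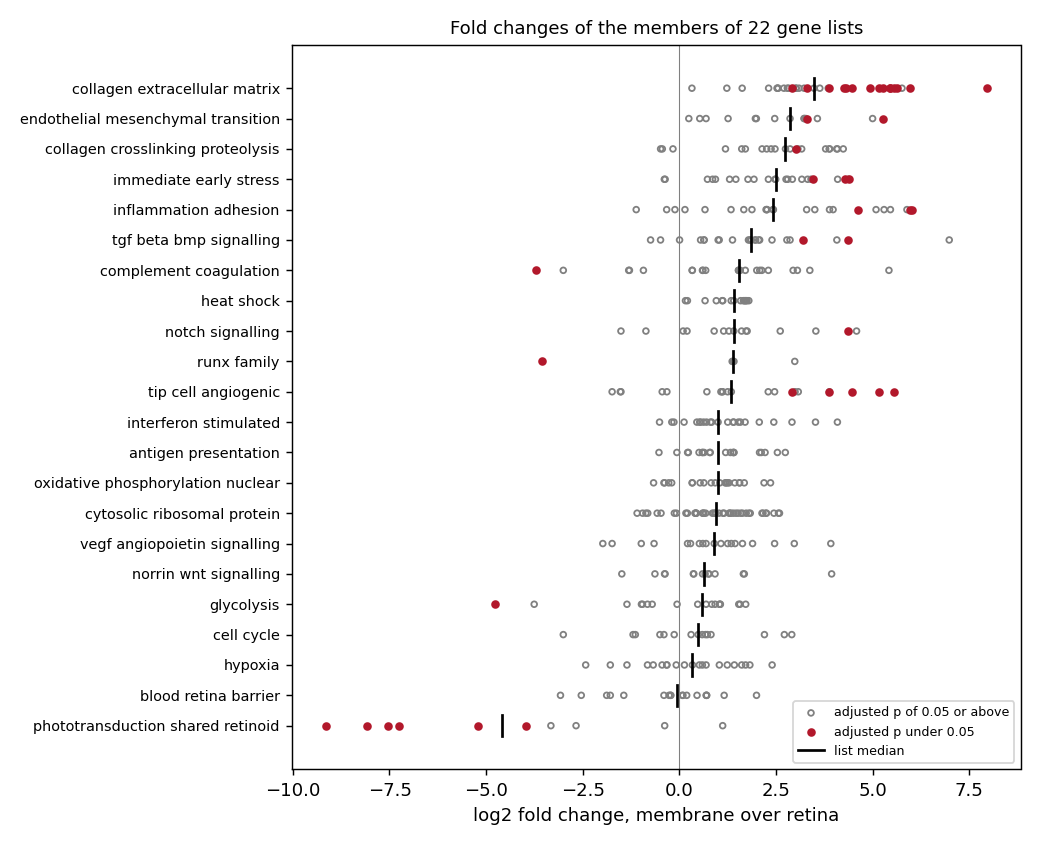
Log2 fold changes (membrane over retina) of the measured members of 22 fixed gene lists; filled points had an adjusted p under 0.05 in edgeR's test and vertical bars are list medians. The collagen and extracellular matrix list had the highest median, 3.48, and the phototransduction and retinoid list the lowest, -4.59.

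RUNX1, a transcription factor studied in aberrant retinal vessels, was at 210 ± 110 CPM (SD, n = 9) in the membranes and 83.1 ± 82.4 CPM (SD, n = 4) in the retinas. Its log2 fold change of 1.37 (SE 0.87) did not pass edgeR's test (adjusted p = 0.393). It was at 26.6 CPM in membrane 5, 44.8 in membrane 9 and 204 in retina 4. Without those 3 libraries, a set chosen on principal components after the data were seen, the log2 fold change was 2.55, with an edgeR adjusted p of 0.0192. Without retina 4 alone it was also 2.55 and did not pass edgeR's test. With limma-voom, an alternative set beforehand, it was 2.23 and passed, and with relative log expression factors, upper-quartile factors and DESeq2 it was 0.20, 0.33 and 0.24 and did not pass. Over all alternatives the adjusted p ranged from 0.0192 to 0.987. RUNX1 lies on chromosome 21 from 36160098 to 37376965 on the minus strand.

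Marker lists showed which cell types the selected cells resembled. Endothelial markers did not separate the groups: PECAM1, which encodes CD31, was at 1482 ± 2552 CPM (SD, n = 9) against 469 ± 632 CPM (SD, n = 4), with a log2 fold change of 1.65 (edgeR adjusted p = 0.434). VWF had a log2 fold change of 0.91 and ROBO4 of 1.94, and edgeR called 0 of the 22 members, also adjusted over the list alone and at an unadjusted p under 0.05, while DESeq2 called 1 lower and limma-voom 0. The endothelial score differed by 0.50 (exact permutation test, adjusted p = 0.775). It was 2.88 in membrane 4 and 3.87 in membrane 5, and between 6.66 and 7.88 in the other membranes. In the retinas it ranged from 4.13 in retina 4 to 7.96 in retina 1. With 1 library left out the log2 fold change ran from 0.66 to 3.21 for PECAM1, from 0.64 to 2.62 for VWF and from 1.56 to 3.78 for ROBO4, highest in each without retina 1, and the score difference from 0.11 to 1.22. None of these passed.

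The fibroblast and myofibroblast score was 3.88 higher in the membranes (6.27 ± 1.12 against 2.39 ± 0.76, SD), in 9 of 9 membranes above the highest retina (exact permutation test, adjusted p = 0.00746, raw p = 0.0014, the smallest the 715 splits can give). Of its 13 genes 6 rose, and 9 adjusted over the list alone; 4 of the 6 also stood in the matrix list. Among pericyte and smooth muscle markers PDGFRB rose by 4.46 and NOTCH3 by 4.36, 2 of 11 (3 adjusted over the list alone; calls lost in 15 of 31 and 18 of 30 alternatives), while RGS5 had a log2 fold change of 2.09 (edgeR adjusted p = 0.205). Their score was 1.22 higher and did not pass the exact permutation test (adjusted p = 0.124).

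Rod, cone, inner neuron and pigment epithelium scores were lower in the membranes, and the Müller glia score did not pass. The rod score was 0.89 ± 0.72 (SD, n = 9) in the membranes and 5.96 ± 2.46 (SD, n = 4) in the retinas, a difference of -5.08 with 9 of 9 membranes below the lowest retina (exact permutation test, adjusted p = 0.00746). Of 14 rod genes 11 fell and 12 did so adjusted over the list alone. GNAT1, rod transducin, fell by 6.91 and PRPH2, peripherin, fell by 7.62. The cone score differed by -1.73 (adjusted p = 0.00746), the inner retinal neuron score by -1.89 (0.0179), the pigment epithelium score by -1.09 (0.0261) and the erythroid score by -1.52 (0.0168), all by exact permutation tests. The pigment epithelium score lost its call in 10 of 21 alternatives. The sizes of the cone, inner neuron, pigment epithelium and erythroid differences cannot be set against the log2 difference of -3.13 in olfactory receptor reads given below. The scores average log2(CPM + 1) over genes, while that value is of summed reads without a pseudocount. Over the alternatives the cone, inner neuron, pigment epithelium and erythroid differences reached -4.38, -2.55, -3.19 and -4.48. Olfactory receptor reads were not used as a covariate for the scores, so background was not tested apart from them. Of 11 cone, 22 inner neuron, 10 pigment epithelium and 9 erythroid genes scored, 3, 7, 4 and 1 passed the low-count filter. Without retina 3, whose cone score was 4.10 against 1.06 to 2.23 in the other retinas, the cone difference was -1.04 and passed. By edgeR 0 of 3 cone genes, 1 of 7 inner neuron genes (CABP5), 1 of 4 pigment epithelium genes (LRAT) and 0 of 1 erythroid gene fell. CABP5 had a log2 fold change of -5.02, and of -1.05 without retina 3, and lost the call in 13 of 28 alternatives. Adjusted over the list alone 0, 2, 1 and 1 fell. At an unadjusted p under 0.05, 1, 3, 1 and 1 were lower, with 0, 1, 0 and 0 called lower by DESeq2 and 1, 4, 2 and 0 by limma-voom. The Müller glia score differed by -0.11 (exact permutation test, adjusted p = 0.937).

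Leukocyte and platelet marker scores did not pass the exact permutation test. The difference was 0.98 for monocytes and macrophages (adjusted p = 0.714), -0.63 for microglia (0.714), 0.40 for T and NK cells (0.714), 0.14 for B and plasma cells (0.788), -1.76 for neutrophils (0.124), -0.86 for platelets (0.124) and -0.02 for lymphatic endothelium (0.979). The neutrophil receptor gene FCGR3B fell by 4.52, the called member of its list. The macrophage gene LYZ was at 629 ± 521 against 176 ± 104 CPM (SD; log2 fold change 1.83, edgeR adjusted p = 0.273).

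**Figure D3:**
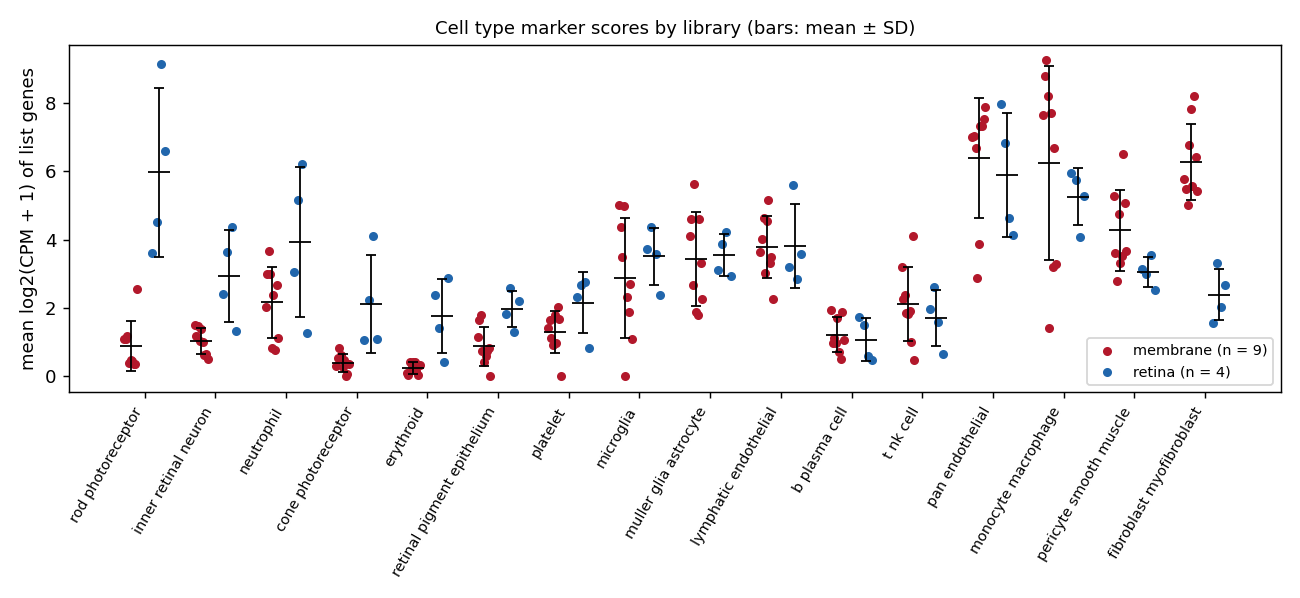
Cell type marker scores, the mean log2(CPM + 1) of each list, in the 9 membrane and 4 retina libraries; points are libraries and bars are means ± SD. The fibroblast score was higher in 9 of 9 membranes, and the rod score lower in 9 of 9, while macrophage scores in the membranes ran from 1.43 to 9.24.

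Reads on 370 olfactory receptor genes, which are silent in most tissues, were taken as a measure of background. They fell on 280, 327, 130 and 48 of these genes in retinas 1 to 4. In membranes 1 to 4 they fell on 260, 152, 225 and 137 genes. In membranes 5 to 9 the 764, 2241, 303, 1044 and 1956 reads fell on 62, 44, 12, 67 and 28 genes. In retina 4 the 899 reads fell on 48. The reads were therefore not evenly spread in membranes 5 to 9 and retina 4. They made up between 67 and 904 CPM of the unscaled library in membranes 1 to 8, 7825 in membrane 9, and between 2521 and 9416 in the retinas. The log2 difference was -3.13 (exact permutation test, p = 0.00839), an 8.73-fold higher geometric mean in the retinas. With this measure as a covariate, an alternative added after the data were seen, edgeR called 74 genes higher and 23 lower, among them 11 of the 66 called higher and 19 of the 403 called lower without it.

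**Figure D4:**
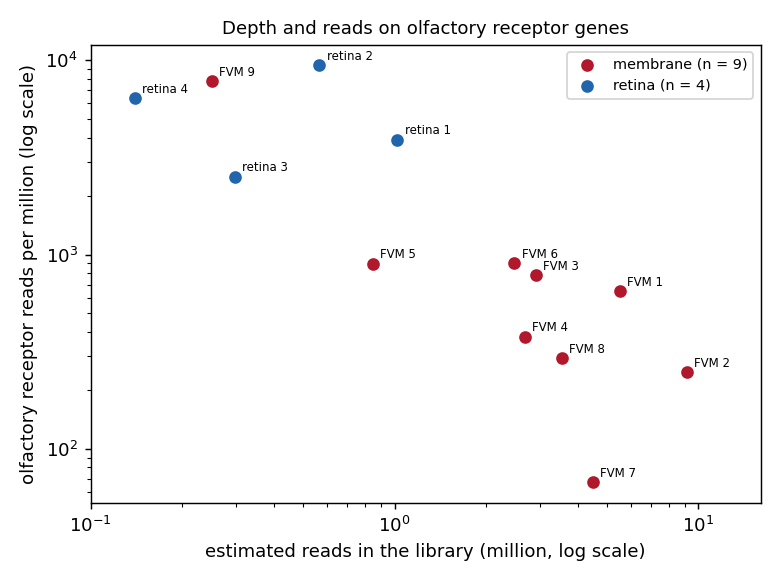
CPM of the unscaled library on olfactory receptor genes (log scale) against the estimated reads of each library (log scale), for 9 membranes and 4 retinas; each point is a library. The 4 retinas and membrane 9 lay at 2521 CPM or above, and the other membranes at 904 or below.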

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

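The tests of retina 4, of depth and of the marker correlations were chosen only after the results they bear on were seen; the background test and the splits were set out before their outcome was known. In 14 of 170 groups of values (8.24%) a library lay far from the others by Dixon's criterion. Chance gives about 1 in 20 for normally distributed values, but many values here were 0. A single nonzero value in a group is then always flagged, as for SAG in membrane 9, OXTR in retina 1 and SNAI2 in retina 2. The share therefore does not show more outlying values than chance gives. Membrane 9 stood apart for rod genes, with a rod score of 2.57, SAG at 14.95 CPM and ABCA4 at 14.95 CPM, and for TIMP1, an inhibitor of metalloproteinases, at 5793 CPM. Membrane 5 stood apart for fibronectin (FN1), at 64590 CPM against at most 12150 CPM in the other membranes, and for the immediate-early gene FOSB, at 36.88 CPM. Among genes nearly absent from membranes, GSTM2P1 was at 6.81 CPM in membrane 1, IMPG1 at 0.825 CPM in membrane 4 and ARGFXP2 at 1.59 CPM in membrane 3. Retina 4 stood apart for ARGFXP2, at 554.7 CPM, for HSPA8, a constitutive chaperone, at 98.3 CPM, and for CXCL2, at 0 CPM. A count of 0 in retina 4 allows up to 21.4 CPM, above CXCL2 in every other retina (10.05 to 16.41 CPM), so depth alone can give that flag. Retina 1 had the single nonzero OXTR value among the retinas, 1.64 CPM, and retina 2 that of SNAI2, 7.44 CPM.

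The 403 genes lower in the membranes included rod genes such as SAG and PDE6A, and many outside the retinal lists. Retina 4, the shallowest library, had the highest retina level for 226 of the 403, and 72 of them were still called without it, against 333, 252 and 290 without retinas 1, 2 and 3, so scattered high counts in that library may account for many of these calls. For the rod genes the values argue against this, since the lowest rod score among retinas 1 to 3 was 3.60 and the highest of any membrane 2.57. An even background such as genomic DNA stays open: over the 354 of these genes with a gene model, retina reads were a median of 2.80 times (quartiles 1.69 and 5.14) what the olfactory receptor genes predicted from exon length, between the bounds set for and against it, with 108 genes under 2 times and 94 above 5 times. In retina 4 the olfactory receptor reads fell on 48 of 370 genes, so there they were not evenly spread. RNA of photoreceptors carried through the CD31 selection of whole retina is a candidate source for the rod genes. The difference in tissue was not tested apart from it. Retina means were 911 CPM for PDE6A and 502 CPM for GNAT1. By library PDE6A was at 110.8 and 175.5 CPM in retinas 1 and 2, and at 2542 and 814.5 CPM in retinas 3 and 4.

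The matrix genes were higher in the membranes, with COL1A1, COL4A1 and POSTN among them. Shallower retina libraries as the whole cause are argued against by thinning, after which the median log2 fold change of the list was 2.83, still past the camera threshold. Fibroblast-like cells in varying number, which a CD31 selection should remove, may contribute: across the 9 membranes the mean level of 26 matrix genes had a Spearman rho of 0.233 with 6 fibroblast markers outside the list (exact permutation p = 0.552, Pearson r 0.214, p = 0.576), and r was -0.36 without membranes 5 and 7. For 14 pericyte and smooth muscle markers rho was 0.317 (exact permutation p = 0.41, Pearson r 0.39, p = 0.3), and r was -0.00523 without membranes 1 and 7; adjusted over these 2 relations each rho had p = 0.552 and each r p = 0.576. With 9 libraries these correlations leave both cell types, and a higher level in the endothelial cells themselves, open.

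Chance assignment of the libraries is argued against for the counts of genes, though only 100 of the 715 splits were run. The other split that called most genes, 140, set membranes 6 to 9 against the rest. Of 100 splits of the 13 samples into 9 and 4, drawn with the real one among them, 1, the real split, gave as many as 469 changed genes (highest other 140), 1 gave as many as 66 higher (highest other 45) and 1 as many as 403 lower (highest other 104). For the count of 13 gene lists 3 of 100 splits gave as many (highest other 13), so it passed the bound set for it, with 2 other splits level. Yet camera at the preset correlation called many lists in splits that called 0 genes. The split of membranes 1, 2, 6 and 7 called 13 lists, and that of membranes 2, 3 and 4 with retina 2 called 11. A list that passed camera at the preset correlation alone is therefore weak evidence of a difference.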

How the results depend on the processing

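The alternatives that thin the libraries, leave out sets of libraries, sum the scores or use olfactory receptor reads were chosen after seeing the data. The matrix list and the phototransduction list kept their direction and their call in every alternative in which they were tested, with medians of 2.83 to 4.53 and -6.84 to -2.18. Counts of genes did not hold. Against 66 higher, 403 lower and 469 in all, edgeR called 40, 880 and 920 with relative log expression factors, 673 lower and 724 in all with upper-quartile factors, and 5, 177 and 182 with pan-endothelial factors. DESeq2 called 312, 1174 and 1486, limma-voom 434, 1513 and 1947, and edgeR without a low-count filter 249, 2412 and 2661; an average of at least 10 CPM gave 100 higher. An adjusted p under 0.01 left 10, 126 and 136, a test against a 2-fold change 30, 231 and 261, and 1 surrogate variable 40, 126 and 166. Retinas 1 and 2 alone gave 1, 7 and 8, and retinas 3 and 4 alone 17 higher and 310 lower. Without the 3 libraries under 300000 reads there were 5, 9 and 14, and 0 cell type scores passed the exact permutation test (7 at an unadjusted p under 0.05; 45 splits allow no p below 0.0222). Without membranes 5 and 9 and retina 4 there were 214 higher and 716 in all, without membranes 4 and 5 there were 116 higher, after thinning 21, 136 and 157, and with olfactory receptor reads as a covariate 23 lower and 97 in all. Leaving out 1 library gave 20 to 173 higher (20 without retina 4, 24 without retina 2, 29 without retina 3, 41 without retina 1, 35 and 38 without membranes 1 and 2, 165 and 173 without membranes 5 and 9), 145 to 551 lower (145 without retina 4, 254 and 253 without membranes 1 and 2) and 165 to 716 in all. The correlations of same-numbered samples were 0.0358, -0.0309, -0.0374 and 0.00617, which showed no pairing. They cannot exclude it, as their power to find a pair was not shown. With the replicate number as a block over samples 1 to 4 there were 203 higher and 226 lower. In those samples without the block there were 412 and 553. Of 13 gene lists 2 were called with an estimated correlation, 5 by fry and 6 after thinning. Of 6 cell type scores 1 passed with pan-endothelial factors, and 3 to 6 with 1 library left out (3 without retina 2). Some directions turned. The cell cycle median was -0.20 with relative log expression factors, -0.24 with pan-endothelial factors and -0.14 to 0.78 with 1 library left out. The hypoxia median was -0.24 with relative log expression factors, -0.66 after thinning and -0.71 with the covariate. The blood-retina barrier median was 0.35 with pan-endothelial factors, 1.87 with retinas 3 and 4, 0.19 without membranes 4 and 5, and -0.33 to 0.62 with 1 library left out. After thinning the glycolysis median was -0.12 and the Norrin and Wnt median -0.62; with the covariate the latter was -0.19 and the complement median -0.42. F8, called lower at -3.70, was at 0.13 with pan-endothelial factors; CD74, the class II invariant chain, went from 1.32 to -0.52 with the surrogate variable, and ALDOC, a neural aldolase, from -3.76 to 1.45 with retinas 1 and 2 and 1.51 without the 3 shallow libraries, where PECAM1 went from 1.65 to -0.20 and VWF from 0.91 to -0.15. The Müller glia score difference was 0.93 with summed CPM, 0.25 without the shallow libraries, 0.0468 without membranes 5 and 9 and retina 4, and -0.40 to 0.15 with 1 library left out. The lymphatic score difference was 0.82 with summed CPM and -0.31 to 0.58 with 1 left out, that of B and plasma cells -0.28 and -0.11 without those sets of 3 and -0.0148 to 0.36 with 1 left out, that of the endothelial list -0.95 without the shallow libraries and -0.22 after thinning, and that of T and NK cells -0.0164 after thinning. The cause was not tested for these changes. Over single genes 1583 values kept direction and side of the threshold, 356 lost and 88 gained a call and 6 turned. FN1, NOTCH3, IL1B, SNAI2, SPARC and F8 lost the call (F8 in 1 case with its direction turned) in 19 of 30, 18 of 30, 18 of 31, 17 of 30, 17 of 31 and 17 of 31 alternatives. A count of 3 reads equalled 21.4 CPM in retina 4, the shallowest library.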

Other observations

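Macrophage genes varied widely between membranes. The macrophage score was between 6.68 and 9.24 in membranes 1, 2, 3, 4, 6 and 8 and was 1.43, 3.20 and 3.28 in membranes 5, 7 and 9. LYZ, the lysozyme of monocytes and macrophages, was at 1431 CPM in membrane 3 and 36.9 CPM in membrane 5, and MSR1, a scavenger receptor, at 1203 CPM and 8.85 CPM. MSR1 and SIGLEC1, another receptor of macrophages, had log2 fold changes of 3.64 and 4.24 against the retinas without passing edgeR's test (adjusted p = 0.111 and 0.0928).

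Single membranes had distinct leading genes. Membrane 4 held 24860 CPM of IL1B and 2688 CPM of CXCL2 with 44.9 CPM of VWF. Membrane 5 held 2060 CPM of LOX, with 114 CPM of VWF and 26.6 CPM of RUNX1. Membrane 9 held 7953 CPM of PECAM1, 6660 CPM of VWF and 2257 CPM of LOX, at 249976 reads. Values of some vessel barrier and coagulation genes that did not pass edgeR's test follow: OCLN, a tight junction protein, had a log2 fold change of -3.07 (adjusted p = 0.0725), the glucose transporter gene SLC2A1 of -1.79 (0.197) and THBD, thrombomodulin, of 3.06 (0.0691).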
